A study of Mus musculus with 6 samples.

How the data were processed

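RNA was measured in 6 libraries of macrophages sorted from injured mouse sciatic nerve, 3 of EGFP+ (resident) and 3 of ECFP+ (recently recruited) cells. Per the labels' protocols, each library came from 3 pooled mice and about 400 cells, cDNA was made with the SMART-Seq v4 kit and 18 cycles of pre-amplification, and sequencing libraries were made with Nextera XT and sequenced in paired-end mode in 2 runs. Which run each library was in is not given in the sources used here, so a difference between runs cannot be told apart from one between groups. This method reads whole transcripts and carries no molecular identifiers, so counts are of amplified fragments and not of molecules.

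The authors deposited a table with expected counts per gene and a second table with FPKM per gene, identified per the file headers and the values. Expected counts, which need not be whole, were deposited by the authors without further normalization. The deposited FPKM values are scaled by the authors to library size and transcript length. Per the submitters' processing notes the tools named were FastQC, Trimmomatic, STAR 2.5.3a, RSEM 1.2.28, DESeq2 and edgeR, and the genome build was mm10. The gene annotation and the use of strand are not given in the sources used here. RSEM divides reads that match several genes between them, so values of near-identical copies depend on that division.

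The table of expected counts had 24848 rows. In 26 of them the symbol was a date, in March or September, as spreadsheets make of symbols of the March and Sept gene families. These rows were left out of library sizes and tests. They held 0.121 to 0.138% of each library. Of the 24822 remaining symbols 24201 were matched to a RefSeq gene table of the mm10 build for coordinates and overlapping genes, and 11140 of the 11354 tested genes were. The table holds no mitochondrially encoded gene. Total expected counts were 16688848 to 27547336 per library, and 3 counts correspond to 0.105 to 0.179 CPM. Such floors cover counting error only.

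Expected counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM normalization, the filterByExpr filter, robust estimation and the group as the only term, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM has a prior count of 2. A fold against a group with no counts was set against 3 counts in each library of that group. Replicates are separate pools of mice, as the design text states. Whether the resident and recruited library of 1 number came from the same mice is not given in the sources used here.

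Gene lists were fixed before the data were examined: 16 programme lists and 13 lists of other cell types. Beside them stood the gate and reporter genes and sex-linked genes, which were not tested as lists. Each list with at least 5 tested genes was compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and adjusted within its family of lists. Camera with an estimated correlation and fry were alternatives. The mean log2 CPM of each list was also computed per library. With 3 libraries against 3 there are 10 splits, so an exact permutation test of a single value cannot go below p = 0.1.

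The genes named were set by a rule fixed before the data were examined. It took the gate and reporter genes, then up to 12 genes per direction with the widest fold among those past the threshold, with at least 10 CPM in the higher group and no overlap of libraries. From each programme list it took up to 4 members past the threshold, or the 2 most abundant where none passed, and from each other cell type list the 2 most abundant. Gene models without a name were left out. Other genes named are marked as chosen after their values were seen, except Xist and Ddx3y, which were listed beforehand to compare the pools of animals.

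The procedure was tested on simulated data with 200 changed genes in each of 5 simulations. Each gene had its mean and a single spread from these libraries, the same for both groups. The real libraries varied more in the resident group (biological coefficient of variation 0.605, against 0.286 in recruited libraries). The shares below therefore may not hold for these data. At 2-fold, 4-fold and 8-fold, 24.8, 64.8 and 75.5% of the changed genes were called and 93.7, 97.3 and 94.5% had the right sign, with 31 false calls over all simulations and a median of 11031 genes tested. A shifted list was called in 5 of 5 simulations and a random list in 0 of 5. The simulated genes were drawn independently of each other. This check therefore says nothing on the list test where genes of a list are correlated.

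The alternatives were DESeq2 size factors and upper-quartile factors, no filter and a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of 1 or more in 3 libraries and on log2(FPKM + 1) for all genes, a replicate block, no robust estimation, an adjusted p of 0.1, and each library left out in turn. Added after seeing the data were limma-voom with library weights, both outlying resident libraries left out (the remaining resident library then being assumed to vary like the recruited ones), and removal from each library of a smooth trend on transcript length and GC. Lengths were those of the longest GENCODE transcript of each symbol, found for 98.9% of tested genes.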

Results

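Macrophages were sorted from the sciatic nerve of Macblue x Cx3cr1-EGFP reporter mice 14 days after CCI, the nerve injury named in the labels, and their RNA was sequenced. Cells carrying CD64 and CD11b and lacking SiglecF and Ly6G were divided by reporter. EGFP+ cells stood for resident macrophages and ECFP+ cells for recently recruited macrophages, both from injured nerves. Each group had 3 libraries, each from a pool of 3 mice and about 400 cells. The libraries held 27547336, 19941233 and 22365809 expected counts in resident replicates 1 to 3 and 16688848, 21314935 and 20038393 in recruited replicates 1 to 3. Genes with at least 1 count numbered 12356, 11436 and 11877 in the resident libraries and 12282, 12460 and 13071 in the recruited ones. All differences below are recruited minus resident, so a negative log2 value is a gene higher in resident macrophages.

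The genes behind the gate and the reporters came first. Csf1r, the receptor for the main macrophage growth factor, was read at 1233 ± 243 CPM, counts scaled to library size (SD, n = 3), in resident and 1441 ± 228 CPM (SD, n = 3) in recruited macrophages. Fcgr1, which encodes CD64, stood at 184 ± 45.8 and 159 ± 30.4 CPM. Itgam, which encodes CD11b, stood at 515 ± 161 and 946 ± 153 CPM, with no overlap between the groups (log2 difference 0.88 ± 0.23 SE, adjusted p = 0.137). Cx3cr1, the fractalkine receptor whose locus carries EGFP in these mice, was read at 91.8, 33.5 and 51.6 CPM in the resident libraries and at 58.3, 35.3 and 9.48 CPM in the recruited libraries (adjusted p = 0.557). Siglecf, which the gate was set against, had means of 2.53 and 3.21 CPM, with 6.23 CPM in resident replicate 2 and 6.16 CPM in recruited replicate 2. Ly6g had no count in any of the 6 libraries, where 3 counts would be 0.105 to 0.179 CPM. None of the tested gate and reporter genes passed the threshold.

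Resident macrophages carried more transcript of C1qa, C1qb, C1qc, Cd74, H2-Aa, H2-Ab1, Gpr34, Fcrls, Stmn1, Cdc20 and Nusap1. Recruited macrophages carried more Cd274, Cd38, Plpp3, P2ry2, Stoml1, Tnfaip2 and Lox. Of 11354 genes tested, 36 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 29 of them higher in resident and 7 higher in recruited macrophages, and all 36 differed by at least 2-fold. At an unadjusted p under 0.05 there were 1905 genes, 982 higher in resident and 923 higher in recruited cells. The libraries of the 2 groups did not overlap for 2822 tested genes, or 24.9%. Over all splits into 3 and 3 the mean share is 10% where no values tie. Genes are not independent, so the share of a single split can lie far from that mean. The shares of the other splits were not computed. DESeq2 called 723 genes, all 36 among them. In edgeR, leaving out resident replicates 1, 2 or 3 gave 580, 3 or 5 genes, and leaving out recruited replicates 1, 2 or 3 gave 1, 0 or 13. Without recruited replicate 2, 603 and 655 genes had an unadjusted p under 0.05. The direction of the 29 called genes that the naming rule took held in each of these fits. The libraries of these genes did not overlap between the groups, so leaving a library out could hardly turn it, and this is no sign of stability. A fit without resident replicates 2 and 3, added after the data were seen, leaves 1 resident library, which is assumed to vary like the recruited ones.

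Among the genes past the threshold that the naming rule took, Hpgd and Gpr34 differed most toward resident macrophages. Hpgd, the enzyme that breaks down prostaglandin E2, was 15.7-fold higher in resident cells, at 56.6 ± 40.1 against 3.60 ± 0.354 CPM (SD, n = 3; log2 difference -3.97 ± 0.57 SE, adjusted p = 0.0383). The resident libraries stood at 18.5, 52.9 and 98.5 CPM, and the log2 difference was -3.30 without resident replicate 3 (adjusted p = 0.0800) and -2.36 without resident replicates 2 and 3 (adjusted p = 0.0856). In that last fit it was -2.73 for Ccl12, -2.38 for Cdc20 and -1.87 for Clec4b1, none past the threshold, and 3.65 for Stoml1 (adjusted p = 0.0174). Hpgd lies on chromosome 8 at 56294552 to 56321046 (mm10). Gpr34, a lysophosphatidylserine receptor of microglia, was 14.1-fold higher, at 68.1 ± 24.8 against 4.84 ± 1.30 CPM (log2 difference -3.81 ± 0.35 SE, adjusted p = 0.0103). Its place is chromosome X, 13622650 to 13640859. Ccl12, a monocyte-attracting chemokine, was 11.4-fold higher, with resident libraries at 42.9, 100.1 and 77.8 CPM and recruited libraries between 2.43 and 10.7 CPM (adjusted p = 0.0493). Fcrls, an Fc receptor-like gene that marks microglia, was 5.45-fold higher, at 415 ± 114 against 76.1 ± 24.5 CPM (adjusted p = 0.0184). Clec4b1, a C-type lectin, was 6.61-fold higher, Slamf9, a signalling lymphocyte activation family receptor, 6.03-fold, and the membrane gene Smagp 5.04-fold (adjusted p 0.0383, 0.0184 and 0.0251). Tmem176a and Tmem176b, neighbouring membrane genes of antigen-presenting cells on chromosome 6, were 5.32-fold and 4.43-fold higher. Their annotated spans overlap, so their values are not independent.

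**Figure D1:**
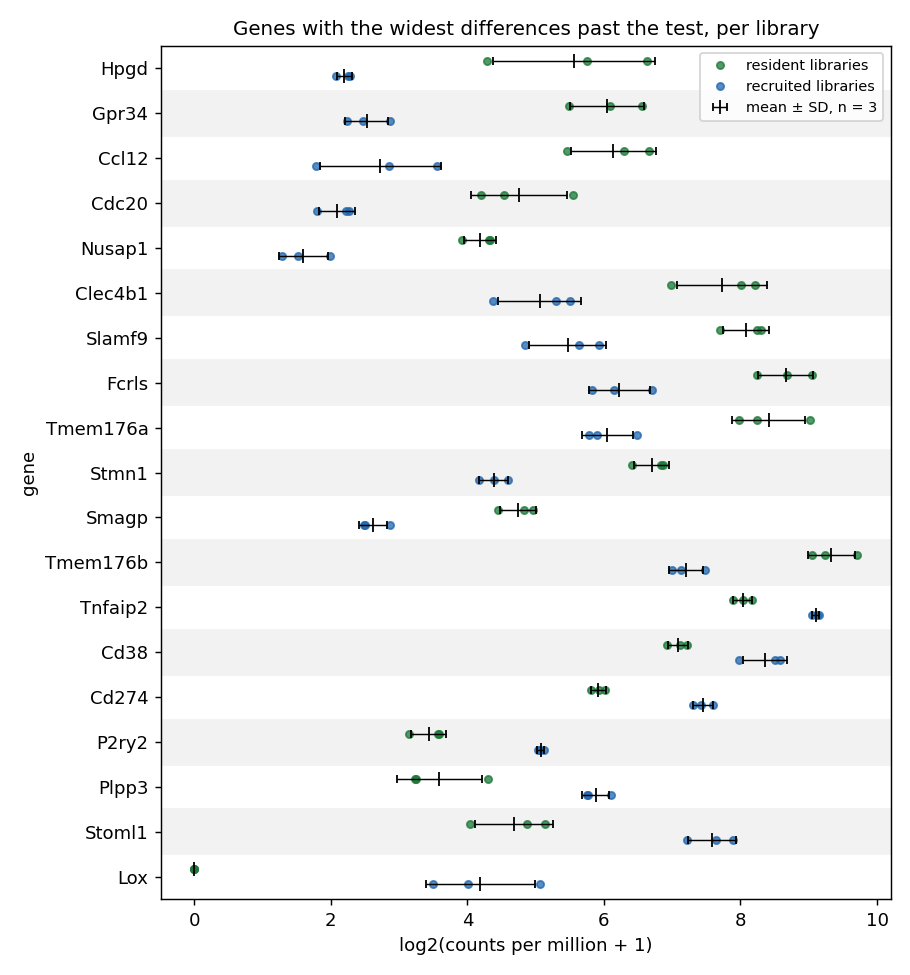
Level of the 19 genes with the widest differences past the test, as log2(CPM + 1) on the horizontal axis with points for single libraries and bars for the mean ± SD of 3 libraries per group. The top 12 genes are higher in every resident library and the bottom 7 in every recruited library, with Lox at 0 in all 3 resident libraries.

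C1q, the recognition molecule of the classical complement pathway, was higher in resident macrophages in all 3 of its chains. C1qa was 3.85-fold higher, at 745 ± 103 against 194 ± 15.4 CPM (SD, n = 3; log2 difference -1.94 ± 0.15 SE, adjusted p = 0.00869), the smallest adjusted p of the whole test. C1qb was 2.71-fold higher, at 3494 ± 607 against 1289 ± 154 CPM, and C1qc 3.00-fold, at 2135 ± 419 against 711 ± 113 CPM (both adjusted p = 0.0184). The 3 genes lie side by side on chromosome 4, between 136880126 and 136898844 (mm10). The other 19 tested genes of the complement and Fc receptor list did not pass, and the list as a whole did not either (22 genes, median -0.14, camera adjusted p = 0.0797, and 0.280 with an estimated correlation), though it passed without recruited replicate 3 (adjusted p = 0.0334) and with fry (adjusted p = 0.0467). Adjusted over the list alone, 3 of its genes were higher in resident and 2 in recruited cells.

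The MHC class II antigen presentation list was higher in resident macrophages as a group. Beside MHC class II genes, which present peptides to CD4 T cells, it holds Cd72, Ctss and the costimulatory genes Cd40, Cd80, Cd83 and Cd86. Of its 16 tested genes 13 had a negative log2 difference and 4 passed the test. These were the invariant chain Cd74, 2.99-fold higher in resident cells at 20271 ± 5583 against 6789 ± 933 CPM (SD, n = 3; adjusted p = 0.0304), H2-Aa (3.09-fold, adjusted p = 0.0383), H2-Ab1 (2.74-fold, adjusted p = 0.0493) and Cd72, a lectin-like inhibitory receptor (4.38-fold, adjusted p = 0.0248). Adjusted over the list alone, 12 genes were higher in resident and 0 in recruited cells. The list median was -1.26 (camera adjusted p = 7.09e-10), and the adjusted p was 0.181 with an estimated correlation. Without resident replicates 2 and 3 the median was -0.61 (adjusted p = 1.15e-04). The mean log2 CPM of the list was 8.30 ± 0.399 in resident and 7.22 ± 0.172 in recruited libraries (SD, n = 3), without overlap. The costimulatory genes of the list, chosen after their values were seen, were uneven. Cd40 was read at 54.0 and 31.5 CPM and Cd83 at 250.3 and 155 CPM, and both were past the threshold adjusted over the list alone, while Cd86 was read at 184 and 190 CPM and Cd80 at 18.3 and 24.4 CPM. Markers of dendritic cells, which also carry MHC class II, went partly along, with Cd209a at 335 ± 243 against 111 ± 56.4 CPM and Mgl2 at 140 ± 96.2 against 32.9 ± 8.15 CPM, neither past the threshold (adjusted p 0.238 and 0.135).

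Cell cycle genes showed the widest shift of any programme list. Of 40 tested genes 38 had a negative log2 difference, with a median of -1.84 (camera adjusted p = 1.05e-18, and 0.0785 with an estimated correlation). Stmn1, which regulates microtubules, was 5.20-fold higher in resident cells at 104 ± 17.7 against 20.03 ± 3.08 CPM (SD, n = 3; log2 difference -2.38 ± 0.21 SE, adjusted p = 0.0103). Cdc20, the activator of the anaphase-promoting complex, was 8.55-fold higher at 28.5 ± 15.2 against 3.32 ± 0.742 CPM (adjusted p = 0.0383). Nusap1, a spindle protein gene, was 8.26-fold higher at 17.3 ± 2.83 against 2.09 ± 0.785 CPM (adjusted p = 0.0356). Over all genes 3 members passed, and adjusted over the list alone 22 were higher in resident and 0 in recruited cells. The mean log2 CPM of the list was 4.42 ± 0.311 in resident and 2.82 ± 0.401 in recruited libraries.

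Lists tied to tissue residence pointed to the resident side. Among the 19 tested genes shared by microglia and nerve macrophages, Gpr34 and Fcrls passed, the median was -0.53 and the camera adjusted p was 7.03e-05 (0.0785 with an estimated correlation). Of the 19 genes 14 had a negative and 5 a positive log2 difference. Tmem119, chosen after its values were seen, was among the positive ones, at 92.8 CPM in resident and 174 CPM in recruited libraries (adjusted p = 0.217). Adjusted over the list alone, 5 were higher in resident and 0 in recruited cells. The list's mean log2 CPM was 6.19 ± 0.252 in resident and 5.40 ± 0.0133 in recruited libraries (SD, n = 3), without overlap. The tissue-resident macrophage list held 24 tested genes with a median of -0.69 (camera adjusted p = 9.24e-04, and 0.350 with an estimated correlation), and its mean level overlapped between the groups. The median was -0.39 after a length and GC correction (adjusted p = 0.00441). Folr2, a folate receptor of perivascular macrophages, was its member past the threshold, 2.86-fold higher in resident cells at 216 ± 27.2 against 75.5 ± 22.3 CPM (adjusted p = 0.0383). Of the 24 genes 17 had a negative and 7 a positive log2 difference. Adjusted over the list alone, 7 were higher in resident and 1 in recruited cells.

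The 7 genes higher in recruited macrophages were led by Lox, the enzyme that cross-links collagen and elastin. Lox had no count in any resident library and stood at 32.4, 15.1 and 10.3 CPM in the recruited libraries, at least 146-fold higher against 3 counts per resident library (adjusted p = 0.0184). That bound covers counting error only. Lox did not pass in limma-voom (adjusted p = 0.144), in limma-voom with library weights (adjusted p = 0.241) or in limma on unfiltered log2(FPKM + 1) (adjusted p = 0.106). Across the alternatives its log2 difference ran from 2.31, on log2(FPKM + 1), to 12. Its place is chromosome 18, 52516060 to 52529867 (mm10). Stoml1, a stomatin-like membrane protein gene, was 7.48-fold higher at 194 ± 45.0 against 26.02 ± 9.59 CPM (SD, n = 3; log2 difference 2.90 ± 0.31 SE, adjusted p = 0.0184). Plpp3, a lipid phosphatase, was 4.91-fold higher at 58.2 ± 8.55 against 11.9 ± 5.96 CPM (adjusted p = 0.0493), and P2ry2, a receptor for extracellular ATP and UTP, 3.29-fold at 32.7 ± 1.08 against 9.91 ± 1.81 CPM (adjusted p = 0.0383). Cd274, which encodes the checkpoint ligand PD-L1, was 2.92-fold higher at 174 ± 18.0 against 59.5 ± 4.55 CPM (log2 difference 1.55 ± 0.14 SE, adjusted p = 0.0103). Cd38, an NAD-consuming ectoenzyme, was 2.44-fold higher at 331 ± 69.1 against 135 ± 13.8 CPM (adjusted p = 0.0383). Tnfaip2, a gene induced by tumour necrosis factor, was 2.10-fold higher at 549 ± 20.3 against 262 ± 25.9 CPM (adjusted p = 0.0184). Several named genes have an annotated neighbour within their span, such as Plgrkt for Cd274, Cask for Gpr34, Elovl1 for Cdc20, Oip5 for Nusap1, Tesk1 for Cd72, Mir5107 for Cd74, Ifi27 for Ifi27l2a and Gm10602 for Folr2. Whether strand was used in counting is not given in the sources used here, so reads from those neighbours cannot be separated.

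Glycolysis and hypoxia-response genes were higher in recruited macrophages as a list, by small steps in many members. Of 30 tested genes 29 had a positive log2 difference, with a median of 0.54 (camera adjusted p = 3.56e-12, and 0.0845 with an estimated correlation). No single member passed over all genes, while adjusted over the list alone 19 were higher in recruited and 0 in resident cells. Pkm, the last kinase of glycolysis, was read at 2536 ± 75.7 CPM in resident and 3690 ± 244 CPM in recruited libraries (SD, n = 3), and Aldoa, an aldolase, at 2109 ± 186 and 2735 ± 247 CPM. The list's mean log2 CPM was 7.39 ± 0.0821 against 7.95 ± 0.083, without overlap. Nuclear-encoded oxidative phosphorylation genes went the other way, with 40 of 43 negative and a median of -0.46 (camera adjusted p = 2.17e-14, and 0.324 with an estimated correlation). None of them passed over all genes, and adjusted over the list alone 19 were higher in resident and 1 in recruited cells. The median was -0.23 after the length and GC correction and -0.13 without resident replicates 2 and 3. The most abundant members differed little: Atp5b was read at 951 ± 105 and 931 ± 71.8 CPM and Atp5a1 at 575 ± 36.7 and 530 ± 35.5 CPM. Across genes, the log2 difference correlated with transcript length (Spearman rho 0.290, genes not being independent), and oxidative phosphorylation transcripts were short, with a median of 1232 against 3295 bases for all tested genes.

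Matrix remodelling genes were higher in recruited macrophages as a list (24 tested, 18 positive, median 0.37 with Lox at its fitted value or at its bound, camera adjusted p = 1.77e-05, and 0.0785 with an estimated correlation). The median was 0.58 without resident replicate 1, 0.58 without resident replicate 3, 0.58 without recruited replicate 3 and 0.73 without resident replicates 2 and 3. Lox passed over all genes, and adjusted over the list alone 8 were higher in recruited and 0 in resident cells. The proteases Mmp8, at 3.89 against 61.8 CPM, and Mmp9, at 3.21 against 38.8 CPM, had adjusted p of 0.138 and 0.117, and are examples chosen after their values were seen. Both also stand in the neutrophil marker list. Lipid and lysosome genes of phagocytes had a median of 0.29 over 31 genes (camera adjusted p = 0.016, and 0.580 with an estimated correlation), and no member passed. This call was lost without resident replicate 1 (median 0.25, adjusted p = 0.210) and without recruited replicate 2 (median 0.09, adjusted p = 0.137). Spp1, which encodes osteopontin, was read at 9330 ± 2997 and 17601 ± 4398 CPM and the protease Ctsb at 13021 ± 2529 and 17198 ± 3099 CPM (SD, n = 3). The chemotaxis and adhesion list had a median of 0.37 over 28 genes (camera adjusted p = 0.0188, and 0.505 with an estimated correlation) and no member past the threshold, with C5ar1 at 837 ± 246 and 834 ± 154 CPM. This call was lost without resident replicate 2 (adjusted p = 0.196), without recruited replicate 1 (adjusted p = 0.0809), without resident replicates 2 and 3 (median 0.16, adjusted p = 0.609) and with no filter on low counts (adjusted p = 0.0507). Adjusted over the list alone, 2 lipid and lysosome genes were higher in recruited cells, and 4 chemotaxis genes were higher in recruited and 1 in resident cells.

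The interferon list held 32 tested genes with a median of -0.35 (camera adjusted p = 0.0436, and 0.700 with an estimated correlation), and its levels overlapped between the groups. The call was lost without resident replicates 1 or 3 (medians -0.10 and -0.12, adjusted p 0.555 and 0.396) without recruited replicate 2 (median -0.21, adjusted p = 0.0819) and on log2(FPKM + 1) (adjusted p = 0.0642). The median was -0.53 without resident replicate 2 and -0.18 after the length and GC correction. Ifi27l2a, an interferon-inducible gene, was 3.73-fold higher in resident cells at 642 ± 67.5 against 172 ± 57.1 CPM (SD, n = 3; adjusted p = 0.0248), and adjusted over the list alone 2 genes were higher in resident and 0 in recruited cells. The remaining lists did not pass in the main test. After the length and GC correction the monocyte, inflammatory and immediate-early lists passed (adjusted p 0.0165, 0.0464 and 0.0266). The inflammatory list also passed without resident replicate 3 (adjusted p = 0.00311) and without resident replicates 2 and 3 (adjusted p = 0.00771), and the immediate-early list without resident replicate 2 or recruited replicates 1 or 3 (adjusted p 0.00205, 0.00304 and 0.0432) and with no filter (adjusted p = 0.0498). Inflammatory cytokine and enzyme genes had a median of 0.18 and a mean of -0.05 over 26 genes, with the camera test on the positive side (adjusted p = 0.339) and Ccl12 as the member past the threshold, and adjusted over the list alone 1 was higher in each group. Across the alternatives the inflammatory median ran from 0.02 to 0.50. Alternative activation genes had a median of -0.24 over 25 genes (camera adjusted p = 0.339), which turned positive without resident replicate 3 (0.19, adjusted p = 0.805) and without resident replicates 2 and 3 (0.32, adjusted p = 0.136), and was -0.05 without recruited replicate 1, -0.13 without resident replicate 2 and -0.47 without recruited replicate 2. Arg1, which encodes arginase, was read at 1940 ± 347 and 2423 ± 451 CPM, and Il1rn, the interleukin-1 receptor antagonist, at 423 ± 168 and 623 ± 118 CPM. Monocyte genes had a median of 0.02 over 30 genes (camera adjusted p = 0.751), with a range of -0.06 to 0.20 and the same sign in 9 of 12 alternatives. The mean log2 CPM of the monocyte list was nonetheless higher in recruited libraries without overlap, at 7.40 ± 0.193 in resident and 7.73 ± 0.131 in recruited libraries (SD, n = 3). Of its members Lyz2, which encodes lysozyme, was read at 33559 ± 1711 and 36183 ± 5478 CPM and Ccl9 at 1880 ± 365 and 1714 ± 277 CPM. Ccr2, the chemokine receptor of classical monocytes, stood at 959 CPM in resident and 485 CPM in recruited macrophages (log2 difference -0.98, adjusted p = 0.0933), an example chosen after its values were seen. Among monocyte genes 5 were higher in recruited and 2 in resident cells adjusted over the list alone, and 2 alternative activation genes were higher in recruited and 5 in resident cells. Immediate-early and heat-shock genes (median -0.12 over 27 genes, camera adjusted p = 0.0797) and sterol synthesis genes (median -0.18 over 22 genes, camera adjusted p = 0.294) had no member past the threshold over all genes or over the list alone. Their medians ran from -0.31 to 0.01, the positive value without resident replicate 3, and from -0.49 to -0.02. Fos and Dusp1, which respond to tissue dissociation, were read at 2150 ± 268 and 2110 ± 448 CPM and at 2485 ± 446 and 2542 ± 819 CPM. Msmo1 stood at 93.1 ± 3.15 and 88.2 ± 3.02 CPM and Ebp at 91.9 ± 11.2 and 81.4 ± 1.15 CPM.

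**Figure D2:**
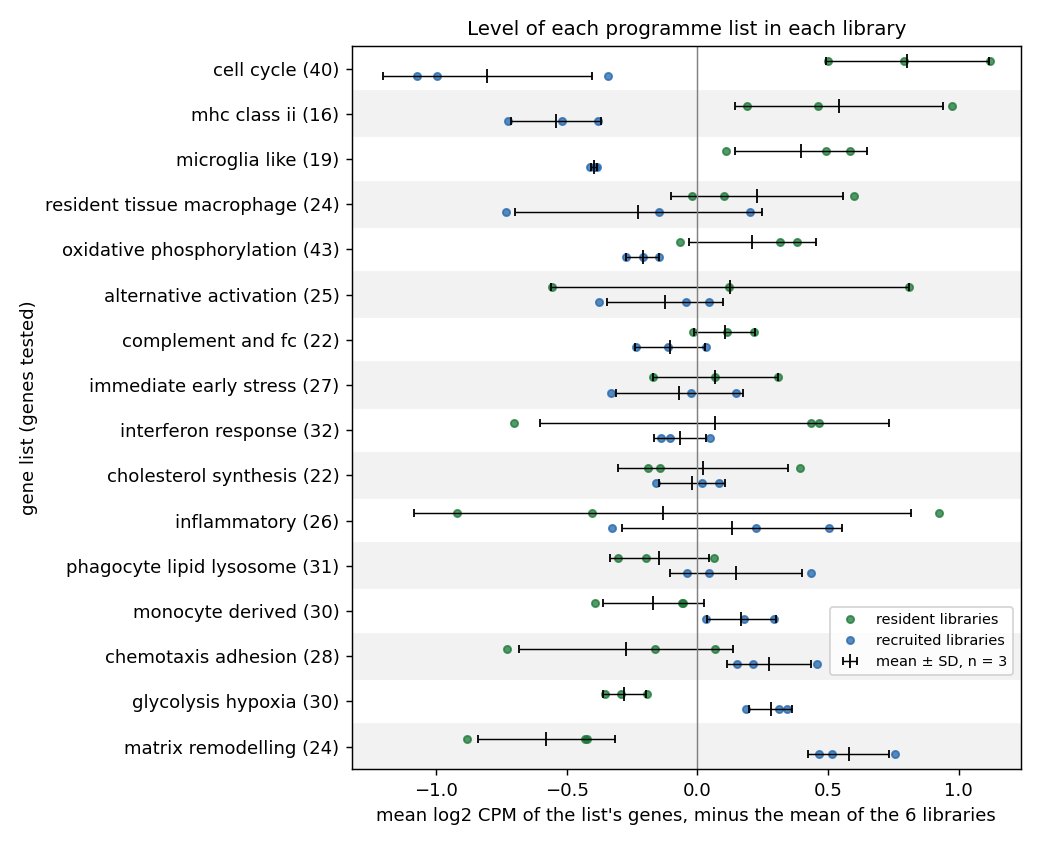
Mean log2 CPM of the tested genes of each of 16 lists in each library, minus the mean of the 6 libraries, with points for single libraries, bars for the mean ± SD of 3 libraries per group and the number of tested genes in brackets. Resident and recruited libraries do not overlap for 8 of the 16 lists, among them cell cycle, MHC class II and glycolysis.

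Over all 16 programme lists, 10 passed the camera test with its preset correlation, 6 of them with a negative and 4 with a positive median. Of these 10 the tissue-resident, phagocyte lipid and interferon lists overlapped between the groups in their mean level per library. With an estimated correlation 0 of the 16 lists passed (4 at an unadjusted p under 0.05), and fry, which asks whether a list's genes move on balance in 1 direction, gave 6. Fry took the complement list and left out the tissue-resident, phagocyte lipid, interferon, oxidative phosphorylation and chemotaxis lists (adjusted p 0.199, 0.317, 0.557, 0.0978 and 0.317). With 3 libraries against 3 an exact permutation test of a list's mean level cannot go below p = 0.1. The other 9 ways of dividing the 6 libraries into 3 and 3 gave between 5 and 9 lists with the preset correlation, against 10 for the division by reporter.

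Markers of other cell types were mostly near the floor, with some exceptions. Fibroblast markers were higher in resident libraries as a list (10 tested genes, median -1.60, camera adjusted p = 0.044, and 0.171 with an estimated correlation), with Col3a1 at 18.8 ± 10.4 against 3.22 ± 0.792 CPM (SD, n = 3; adjusted p = 0.105) and Igfbp6 at 19.1 ± 0.661 against 24.9 ± 3.91 CPM. The fibroblast call was lost without resident replicates 1 or 3 (adjusted p 0.0819 and 0.0670), without resident replicates 2 and 3 (median -0.75, adjusted p = 0.121), with no filter (adjusted p = 0.175), on log2(FPKM + 1) (adjusted p = 0.0579), with fry (adjusted p = 0.0752) and after the length and GC correction (adjusted p = 0.0761). Of the fibroblast genes, 1 was higher in resident and 0 in recruited cells adjusted over the list alone. Neutrophil markers were higher in recruited libraries as a list (7 tested genes, median 0.66, camera adjusted p = 0.0253, and 0.171 with an estimated correlation), with S100a8 at 43.8 ± 24.6 against 69.0 ± 34.4 CPM and Csf3r at 64.6 ± 10.5 against 75.5 ± 18.3 CPM. The neutrophil call was lost without resident replicate 1 (median 0.40, adjusted p = 0.0819), with no filter (median 0.38, adjusted p = 0.175) and with fry (adjusted p = 0.0752). The median was 1.21 without resident replicate 2, 1.25 without resident replicates 2 and 3 and 1.10 after the length and GC correction. Mmp8 and Mmp9 were the 2 neutrophil genes higher in recruited cells adjusted over the list alone, with 0 higher in resident cells. Red blood cell and platelet markers were uneven (5 tested genes, median -3.79, camera adjusted p = 0.0583): Hbb-bs was read at 7.79, 0 and 161 CPM in the resident libraries and at 0, 0 and 10.96 CPM in the recruited libraries, and Ppbp at 140 ± 103 against 54.1 ± 39.4 CPM. The list passed with the replicate block (camera adjusted p = 0.00218), without resident replicates 1 or 2 (adjusted p 0.0307 and 0.0107) and without recruited replicate 3 (median -9.15, adjusted p = 0.0264). The median was -0.10 without resident replicate 3 (adjusted p = 0.4995), -0.91 without resident replicates 2 and 3 (adjusted p = 0.435) and -2.36 after the length and GC correction. Haemoglobin genes have near-identical copies between which reads may be split. Dendritic cell markers had a median of -0.45 over 12 genes (camera adjusted p = 0.193), with 2 higher in resident and 0 in recruited cells adjusted over the list alone, and Schwann cell markers 0.14 over 6 genes (camera adjusted p = 0.957), with Pmp22 at 212 ± 21.7 against 290 ± 179 CPM and Cnp at 74.8 ± 16.2 against 58.9 ± 3.84 CPM. The Schwann cell median ran from -0.19 to 0.43 and kept its sign in 8 of 12 alternatives, turning negative without resident replicate 3, without recruited replicate 3, without resident replicates 2 and 3 and after the length and GC correction. The dendritic list passed without resident replicate 1 (median -0.63, adjusted p = 0.0307) and without recruited replicate 2 (median -1.53, adjusted p = 0.0336), and its median was -0.21 without resident replicate 2, -0.29 without resident replicate 3, -0.01 after the length and GC correction and 1.32 without resident replicates 2 and 3 (adjusted p = 0.255).

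The other cell type lists had fewer than 5 tested genes and were not tested as lists. Cd79b, a B cell receptor subunit, was 4.21-fold higher in resident cells at 25.1 ± 4.73 against 5.96 ± 1.52 CPM (SD, n = 3; adjusted p = 0.0493), while its partner Cd79a, chosen after its values were seen, stood at 0 and 0.0982 CPM and Cd22, a B cell lectin, at 16.4 ± 5.07 and 26.8 ± 9.20 CPM. Il7r was read at 77.1 ± 8.25 and 137 ± 20.1 CPM and Cd2 at 44.5 ± 12.3 and 22.5 ± 5.53 CPM, with the T cell genes Cd3d, Cd3e and Cd3g, chosen after their values were seen, at group means of no more than 0.0823 CPM. Ear2 was read at 136 ± 90.9 and 71.6 ± 32.8 CPM. Kdr and Eng of endothelium, Acta2 and Pdgfrb of mural cells, Hdc and Kit of mast cells, Scd1 and Car3 of adipocytes and Tnni2 and Mylpf of muscle had group means below 10 CPM, and none passed the threshold.

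The 2 groups differed in how alike their own libraries were. The mean correlation of log2 CPM was 0.863 among resident and 0.9504 among recruited libraries, and 0.885 between the groups. The biological coefficient of variation was 0.605 in resident and 0.286 in recruited libraries. The first principal component, with 39.8% of the variance, set resident replicate 2 apart, and the second, with 30.3%, resident replicate 3. Genes at 0 in 1 library but at 10 CPM or more on average elsewhere numbered 6, 24 and 12 in resident replicates 1 to 3 and 3, 4 and 1 in recruited replicates 1 to 3. Xist, expressed from the inactive X chromosome of females, was read at 19.5, 5.56 and 10.2 CPM in resident and at 1.61, 1.86 and 2.12 CPM in recruited libraries (adjusted p = 0.105). The Y-linked Ddx3y stood at 5.38, 20.8 and 14.6 CPM and at 31.4, 34.0 and 32.0 CPM (adjusted p = 0.211). Both genes separated all resident from all recruited libraries, while the Y-linked Uty, Kdm5d and Eif2s3y overlapped between the groups, with Eif2s3y at 6.22, 52.8 and 40.9 CPM and at 35.04, 47.8 and 48.2 CPM. The sex of the pooled mice is not given in the sources used here. A difference in sex make-up between the pools thus cannot be told apart from one between the populations, for any gene or list reported here.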

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

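Added after seeing the data were limma-voom with library weights, the fit without resident replicates 2 and 3, and the length and GC correction. The fit without resident replicates 2 and 3 leaves 1 resident library, assumed to vary like the recruited ones. The 29 called and named genes kept their direction in 19 alternatives, but their calls did not: all 29 passed with DESeq2 size factors, DESeq2, no filter, the filter of 10 CPM and both filtered FPKM scales, and 28 with upper-quartile factors, 27 without robust estimation, 27 with library weights, 22 with limma-voom, 15 with the replicate block, 6 without resident replicates 2 and 3 and 2 on unfiltered FPKM. Leaving out resident replicates 1, 2 and 3 left 29, 3 and 5, and recruited replicates 1, 2 and 3 left 1, 0 and 11. The libraries of these 29 genes did not overlap between the groups, so their direction could hardly turn and is no sign of stability.

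The count of changed genes (36; 7 recruited, 29 resident, all at least 2-fold) was 58 with no filter (18 recruited), 73 at 10 CPM in 3 libraries (22 recruited, 51 resident, 62 at 2-fold), 723 with DESeq2 (317, 406, 331), 99 on log2(FPKM + 1) (27, 72, 83), 60 on log2(FPKM + 0.1) (15, 45, 55), 2 on unfiltered FPKM (0 recruited, 2 resident, 2 at 2-fold; 1006 and 1160 at an unadjusted p under 0.05 in limma), 86 at an adjusted p of 0.1, 65 with library weights (14, 51, 60) and 11 without resident replicates 2 and 3 (5 resident, 11 at 2-fold). With single libraries left out it ran from 0 to 580, with 0 to 254 recruited, 0 to 326 resident and 0 to 296 at 2-fold. The 0 was edgeR's count without recruited replicate 2, where 603 and 655 genes had an unadjusted p under 0.05, and the 580 its count without resident replicate 1. Fits with fewer samples have fewer degrees of freedom. Beyond that the cause was not tested.

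Of the programme lists 10 passed, 0 with an estimated correlation (4 at an unadjusted p under 0.05), 6 with fry (the complement and Fc list among them), 9 on log2(FPKM + 1), 13 after the length and GC correction (with the monocyte, inflammatory and immediate-early lists added) and 8 to 12 with single libraries left out. The interferon median was -0.22 with the replicate block. Of the cell type lists 2 passed, 0 in camera with no filter (3 at an unadjusted p under 0.05), 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 with fry (2), 1 on log2(FPKM + 1), 1 without resident replicates 2 and 3, 1 after the length and GC correction, and 1 to 3 with single libraries left out. The medians of the 10 passing programme lists kept their sign in all 12 alternatives run on them, but without resident replicates 2 and 3 that of MHC class II was -0.61 and that of oxidative phosphorylation -0.13. Among tested lists that did not pass, the alternative activation, Schwann cell, monocyte, immediate-early and dendritic medians kept their sign in 10, 8, 9, 11 and 11 of 12 alternatives. The within minus between group correlation (0.022) was 0.150 over the 1000 most variable genes and -0.000831 to 0.0548 with single libraries left out, turning negative without recruited replicate 2 for a cause that was not tested. The replicate block gave 28 genes (6 recruited, 22 resident), 17 of them among the 36, with 10 programme and 3 cell type lists. Deviations of same-numbered libraries correlated by 0.016, 0.063 and 0.049, and not every library correlated best with its own number, so the numbers were not taken as pairs. The alternative without mitochondrial genes was not run, since the table holds none. Scaling moved the median of all genes by less than 0.1.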

Other observations

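The tests of dendritic cells for MHC class II, of the gene families, of the length trend as the whole cause and of the fit without resident replicates 2 and 3 were chosen after the result was seen. Gene families defined by symbol alone added further groups. Ribosomal protein genes, which build the cytosolic ribosome, had a negative log2 difference (higher in resident macrophages) in 80 of 81 tested members, with a median of -0.75 (camera adjusted p = 2.78e-32, and 0.342 with an estimated correlation). Rpl13a, named after its values were seen, passed over all genes (log2 difference -1.03 ± 0.16 SE, adjusted p = 0.0493). Mitochondrial ribosomal protein genes went the same way in 68 of 75 members (median -0.37, camera adjusted p = 3.74e-11, and 0.407 with an estimated correlation), and no member passed. After removal of the length and GC trend the medians were -0.48 and -0.21.

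Proteasome subunit genes had a median of -0.23 over 38 members (-0.08 after the length and GC correction), and integrin genes, which encode adhesion receptors, a median of 0.53 over 16 members, 11 of them positive (0.42 after the correction; camera adjusted p 0.00029 and 0.0108, and 0.523 and 0.493 with an estimated correlation). Vacuolar ATPase genes, which acidify lysosomes, had a median of 0.29 over 18 members, 13 of them positive (0.28 after the correction, camera adjusted p = 0.00885, and 0.276 with an estimated correlation). Among the 36 called genes, resident macrophages were also higher in Ly86, a partner of the Toll-like receptor homologue CD180 (log2 difference -1.15 ± 0.13 SE, adjusted p = 0.0184), and in Aif1, which encodes the microglial marker IBA1 (-1.26 ± 0.19 SE, adjusted p = 0.0493), genes chosen after their values were seen.

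The MHC class II list, which also holds Cd72, Ctss and costimulatory genes, was higher in resident libraries with the preset correlation. The camera adjusted p was 0.181 with an estimated correlation. Dendritic cells in the resident gate stay open as a source, although the gate took CD64+ CD11b+ cells, which selects macrophages over dendritic cells: the dendritic median lay 0.812 above the MHC class II median, but the bootstrap 95% interval ran from -0.588 to 1.42, with resident and recruited means of 335 and 111 CPM for Cd209a, 140 and 32.9 CPM for Mgl2, 8.14 and 6.56 CPM for Flt3 and 8.63 and 10.2 CPM for Ccr7, the last 2 chosen after their values were seen. Without resident replicates 2 and 3, the libraries that lie farthest from the rest, the MHC class II median was -0.61 (adjusted p = 1.15e-04) and the dendritic median 1.32 (adjusted p = 0.255, against -0.45 with all libraries). That fit leaves 1 resident library, assumed to vary like the recruited ones, so it decides nothing on dendritic cells. The sex of the pooled mice was not tested as a source and also stays open, here as for every other difference between the groups, since Xist and Ddx3y separated them. A difference of the populations themselves may account for the pattern, and remains a hypothesis.

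Resident libraries varied more among themselves. Transcripts missed at random in small inputs stay open as a source. The excess of squared variation over recruited libraries was 0.405 at 1 to 10 CPM and fell with abundance. At 100 CPM or more it was 0.0340 of that value. Squared variation within recruited libraries also fell, from 0.234 at 1 to 10 CPM to 0.0261 at 100 to 1000 CPM. A cause that widened all spread by 1 factor would thus also give a falling excess, so this test does not single out missed transcripts. Red blood cell, platelet and fibroblast transcripts stay open: without those marker lists the mean correlation among resident minus that among recruited libraries was -0.0871, but too few genes were left out to move either correlation (0.863 to 0.864 among resident libraries), so this decides nothing. Input was set to about 400 cells in both groups, per the labels, and a mixed resident population was not tested.

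Oxidative phosphorylation genes were higher in resident libraries as a list with the preset correlation, but the adjusted p was 0.324 with an estimated correlation and 0.0978 with fry, and none of 43 genes passed over all genes. Their transcripts are short, and after removal of the length and GC trend the median moved from -0.43 on the log2 CPM scale to -0.233 (bootstrap 95% interval over genes -0.318 to -0.133). With single libraries left out the corrected median stayed at or below -0.144, so the trend as removed here did not account for the whole pattern. The correction took the longest transcript of each symbol and may leave part of the trend, so the trend as the whole cause is not excluded. Whether the trend gave the greater part of the pattern cannot be told apart either, because the interval spans -0.217, the midpoint between the uncorrected median and 0. With single resident libraries left out the median nearest 0 was -0.346, which argues against 1 resident library as the source, but without both resident replicates 2 and 3 it was -0.13. That value rests on resident replicate 1 alone and so does not tell the 2 libraries apart from the group. Glycolysis genes were higher in recruited libraries as a list with the preset correlation, with 0 of 30 genes past the threshold over all genes and an adjusted p of 0.0845 with an estimated correlation. A shift in energy metabolism between the populations is a hypothesis that these RNA levels do not test.

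The reporter groups were set against the 9 other splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. Each of those splits mixes resident and recruited libraries. A difference between the groups then widens the spread within each side and lowers the count of changed genes. A count of 0 there does not show what chance alone would give. The real split gave 36 changed genes and the highest other split 0, with 7 and 29 by direction against 0 and 0, and 36 against 0 at 2-fold, so that 1 of 10 splits reached each of these counts. For the programme lists the real split gave 10 and the highest other 9, again 1 of 10 splits. For the cell type lists the real split gave 2 and the highest other 2, and 3 of the 10 splits gave as many.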
